A study of Populus tremula x Populus tremuloides with 22 samples.

How the data were processed

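RNA sequencing was done on stem internodes of 3-week-old hybrid aspen, a cross of European and American aspen grown in a greenhouse. The 22 libraries were 5 of wild type (WT), 8 of trees overexpressing Arabidopsis LBD4 (LBD4-OE) and 9 of trees overexpressing Arabidopsis LBD11 (LBD11-OE). Each construct was present as 3 lines. Groups and replicate numbers came from the sample titles. For the last LBD11-OE line the title gives the number 14 and the genotype label the number 3, and the title was used. Nothing in the labels says that replicates of a line were separate trees, so p-values measure only the spread between these samples, which may be technical.

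Per the labels' protocols, RNA was extracted with a column kit including a DNase step, libraries were made after poly(A) enrichment, and fragments were read from both ends on an Illumina HiSeq. The submitters' processing notes name MultiQC, Trimmomatic, HISAT2, Cufflinks and HTSeq, and versions, the genome build and the strand setting of the counting were not given in the sources used here. The authors deposited 1 file per library with the raw read count of each gene, whole numbers from HTSeq per the labels, for 34699 genes that carry Potri identifiers, the scheme used for black cottonwood gene models. Reads of a hybrid of other poplar species were thus counted on identifiers of a related species, and alleles or near-identical copies that map poorly or to several places can be undercounted. Genes that overlap on opposite strands could not be told apart with certainty either. The Arabidopsis transgenes are not among the counted gene models and their levels were not analysed here. The files pair no identifier with a gene name. Coordinates are given as in the files, without a stated base, and no genome sequence was used.

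Total counts per library ran from 23437445 to 41969957. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter (a minimum count of 10 and a minimum total count of 15), robust dispersion estimates and the quasi-likelihood F test. The comparisons between constructs used 25626 genes and 3 group means over all 22 libraries. The comparisons of single lines with WT used 26271 genes and 7 group means, of which WT was 1 and the 6 lines the rest. Differences among the 3 lines of a construct were tested jointly in the same line model. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 with no limit on the fold. CPM values, counts scaled to library size, were computed from the deposited counts with the TMM-scaled library sizes, and their SD is over libraries. Fitted log2 fold changes are given with their standard error (SE). For genes with very few counts in 1 group the ratio of summed counts is given with an exact 95% interval, which covers counting error only.

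Gene lists were fixed by identifier before the data were examined, from general knowledge of the poplar literature, as were the groups, the models, the thresholds, the rule for the genes printed and the alternatives not described as added later. Of the 69 listed identifiers 68 were in the files and 67 were tested. The lists held secondary wall cellulose synthases, primary wall cellulose synthases, enzymes of lignin monomer biosynthesis, xylan synthases, secondary wall transcription factors, regulators of the cambium and of vascular patterning, and a pair of circadian clock genes that stood for sample state. Because no table pairs identifiers with names here, which genes belong to each list could not be checked, and lists are described as a whole without naming members. Further lists that could only have been filled from product names (the LBD family, laccases, cell cycle, phloem, photosynthesis, epidermis, heat shock, defence, hormone response, ribosomal proteins and others) were not tested. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted over the 6 lists of a comparison. The genes printed are the 2 with the largest rise and the 2 with the largest fall per comparison of constructs, among genes past the threshold, at a mean of at least 5 CPM in the higher group and with the same direction in each line. The rule also named up to 4 members per list, which are not printed singly for the reason given above.

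The same scripts were tested on simulated counts with known changes in 200 genes. Of simulated 2-fold changes 92% were recovered for LBD4-OE against WT, 86% for LBD11-OE against WT and 96% for LBD11-OE against LBD4-OE, and of simulated 1.25-fold changes 16%, 30% and 26%. For line LBD4-OE-14, which has 2 libraries, 56% of 2-fold and 26% of 1.5-fold changes were recovered. The counts of every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.91, so no library was merged with another as a repeated deposit. This does not show that the libraries came from separate trees.

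The alternatives tried were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma voom, fits with only the groups compared, line means in place of construct means, line as a random block, the replicate number as a block, stricter thresholds, and leaving out each library or line. As both constructs were compared with the same WT libraries, overlaps were set against 20 simulations of unchanged groups and against the 20 ways of sharing out the WT libraries between the comparisons. After the data were examined, further fits were added because a group of co-varying genes divided the libraries into 2 sets that cross the constructs. They took the library set as a term, used only the 15 libraries of the larger set or only the 7 of the smaller, compared lines pairwise, or left out WT replicate 3 and LBD4-OE-11 replicate 1, which lay apart on principal component 2. The labels give no batch. The groups of co-varying genes were found by exploring the data and consist of genes that correlate at r above 0.9 with a chosen gene across the libraries.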

Results

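The series asks how the stem transcriptome of hybrid aspen changes when Arabidopsis LBD4 or LBD11 is overexpressed in the xylem. Both genes encode LATERAL ORGAN BOUNDARIES DOMAIN transcription factors, a plant family with roles in organ boundaries and in vascular development. Transcripts of stem internodes were counted in 5 WT libraries, in 8 LBD4-OE libraries (line 11 with 3, line 14 with 2 and line 17 with 3) and in 9 LBD11-OE libraries (lines 1, 2 and 14 with 3 each). The libraries held 23437445 to 41969957 counts each, and between 27836 and 28374 genes had at least 1 count. Principal component 1 carried 32.8% of the variance and placed the 9 LBD11-OE libraries at 19.8 to 56.9, the 8 LBD4-OE libraries at -27.4 to -0.472 and the 5 WT libraries at -49.9 to -34.5. Principal component 2, with 11.3%, set WT replicate 3 (-73.6) and LBD4-OE-11 replicate 1 (-41.3) apart from the rest.

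The comparison of LBD11-OE with WT asks which genes respond to LBD11. Of the genes tested 32.3% changed in the LBD11-OE stems, 4115 upward and 4166 downward. Most changes were small, with a median size of 0.43 on the log2 scale, and 795 genes rose and 526 fell by a factor of at least 2. Of the 8281 changed genes, 8271 had the same direction in each of the 3 lines, which their choice by the pooled difference favours. Past the threshold in every line taken alone, 1394 genes rose and 1257 fell. In limma voom with line as a random block 6197 genes changed, of which 6187 were among the 8281. The test was edgeR's quasi-likelihood F test at an adjusted p under 0.05. Within the 15 libraries of the larger of the 2 library sets described further on, 7137 genes were changed. Within the 7 of the smaller set, which holds LBD11-OE-2 and a single WT library that is assumed to vary like the other groups, 3768 were.

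Genes that were nearly silent in WT became active in LBD11-OE stems. Potri.011G126000 (chromosome 11, 15701321 to 15701888, minus strand) reached 6.57 ± 3.62 CPM (SD, n = 9) and was counted in each LBD11-OE library, with 1846 counts in all against 2 counts in a single WT library. That is a ratio of 554 (exact 95% interval 153 to 4580), with an edgeR adjusted p of 6.689e-09. Potri.005G059900 (chromosome 5, 3782342 to 3787963, minus strand) had 2269 counts in LBD11-OE and 7 in WT, a ratio of 195 (94.3 to 485) with an edgeR adjusted p of 1.014e-06. In total 9 genes went from a mean under 0.1 CPM in WT to at least 1 CPM in each LBD11-OE line, and 1 gene went the other way. The files pair no identifier with a gene name, so what these genes encode is not given here.

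The largest falls in LBD11-OE were those of Potri.011G161500 (chromosome 11, 18660987 to 18663004, plus strand) and Potri.001G109300 (chromosome 1, 8810562 to 8813009, plus strand). The former was at 15.3 ± 11.3 CPM in WT (SD, n = 5) and 0.199 ± 0.196 CPM in LBD11-OE (SD, n = 9), a log2 fold change of -6.24 ± 1.19 (SE, edgeR adjusted p = 5.677e-04). The latter was at 40.5 ± 30.6 CPM in WT and 1.49 ± 1.17 CPM in LBD11-OE, a log2 fold change of -4.78 ± 1.05 (SE, edgeR adjusted p = 0.00180). Both were also near the floor in WT replicate 3, with 0 and 0.531 CPM. Within the smaller set, where this is the sole WT library, Potri.011G161500 had 19 counts over the 3 LBD11-OE-2 libraries and 0 in WT (edgeR adjusted p = 0.799), and Potri.001G109300 had a log2 fold change of 1.56 (edgeR adjusted p = 0.844). Neither passed the threshold in the limma fit with line as a random block, with adjusted p-values of 0.270 and 0.227.

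All 8 listed primary wall cellulose synthases, which make the cellulose of growing cell walls, rose in LBD11-OE stems, by a log2 fold change of 0.20 to 0.84 and a median of 0.44. Of the 22 listed enzymes of lignin monomer biosynthesis 9 rose and 0 fell, with a median of 0.14 and a highest value of 0.76 ± 0.14 (SE), from 910 ± 178 CPM in WT (SD, n = 5) to 1544 ± 254 CPM (SD, n = 9). Of the 5 secondary wall cellulose synthases, which serve wood formation, 3 rose over all genes tested and 4 when adjusted over the list alone, with a median of 0.35. Adjusted over the list alone, the counts for the primary wall and lignin lists were likewise 8 and 9. Within the larger library set 8, 9 and 3 members of these lists rose, and within the smaller set 5, 0 and 2 did, with medians of 0.53, 0.02 and 0.43. The limma camera adjusted p was 3.269e-06 for the primary wall list, 0.00361 for the lignin list and 0.0565 for the secondary wall list. With an estimated correlation between genes no list passed, with adjusted p = 0.135, adjusted p = 0.706 and adjusted p = 0.706 in that order. The lignin list depended on line LBD11-OE-14, without which its camera adjusted p was 0.0673, and within the smaller set that p was 0.947.

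Of the 12 cambium and vascular patterning regulators 5 rose and 5 fell in LBD11-OE, between -0.36 and 0.45 on the log2 scale, and of the 15 secondary wall transcription factors 2 rose and 2 fell, the same counts as when adjusted over the list alone. Of the cambium regulators 1 rose without WT replicate 3, 2 without WT replicate 3 and LBD4-OE-11 replicate 1, and 3 without WT replicate 5, LBD11-OE-1 replicate 1, or line LBD11-OE-1, with 5 lower in each case, while 3 rose and 2 fell without line LBD11-OE-14, and 5 rose and 1 fell within the smaller set. Of the transcription factors 1 to 3 fell when single libraries were left out. The highest value among the transcription factors, 1.65 ± 0.43 (SE, edgeR adjusted p = 0.00473), belonged to a gene at 0.128 ± 0.0696 CPM in WT (SD, n = 5) and 0.399 ± 0.194 CPM in LBD11-OE (SD, n = 9). Camera adjusted p-values for these lists were both 0.851, and its direction was down for both although median and mean lay slightly above 0 (medians 5.503e-04 and 0.0096, means 0.030 and 0.12). Among the 3 xylan synthases 0 passed edgeR's test in LBD11-OE, either over all genes or over the list alone, and 0 passed with DESeq2 or limma voom, while 1 was higher at an unadjusted p under 0.05, and 1 rose within the larger library set, with library set as a term or without LBD11-OE-2 replicate 2, with a median of 0.09 and a camera adjusted p of 0.708. Both circadian clock genes fell, by -0.46 ± 0.09 and -0.72 ± 0.10 (SE), with edgeR adjusted p-values of 5.615e-04 and 5.179e-06. Their median log2 fold change was -0.51 within the smaller set. As this pair stood for sample state, a difference in sample state between LBD11-OE and WT is not excluded as a source of changed genes, and this was not tested.

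**Figure D1:**
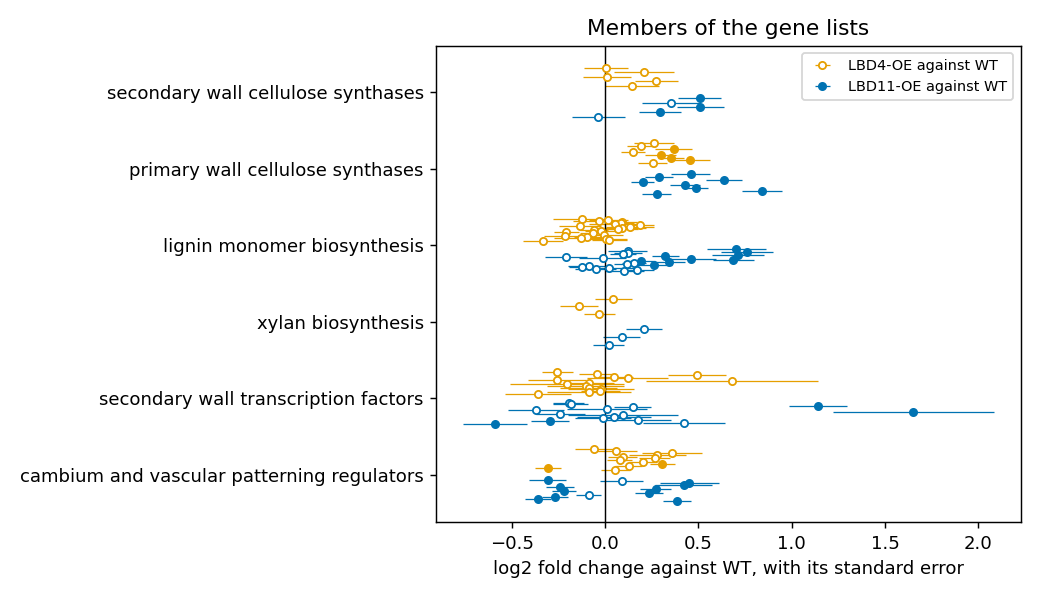
Log2 fold change against WT (horizontal axis) of each member of 6 gene lists, in orange for LBD4-OE and in blue for LBD11-OE, with bars for the standard error and filled points for members past an edgeR adjusted p of 0.05. All 8 primary wall cellulose synthases are filled for LBD11-OE and 4 for LBD4-OE, and 9 of the 22 lignin enzymes are filled, to the right of 0, for LBD11-OE.

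The comparison of LBD4-OE with WT asks the same of LBD4. It changed fewer genes, 694 upward and 403 downward, or 4.28% of those tested, with a median size of 0.40 on the log2 scale. At least 2-fold changes were found for 124 genes that rose and 33 that fell. Of the 1097 changed genes, 1095 had the same direction in the 3 lines, which their choice by the pooled difference favours. Only 44 genes passed the threshold in each line alone, 36 upward and 8 downward. The count moved with the model, to 163 in limma voom with line as a random block (all 163 among the 1097, where limma voom without the block gave 1040), to 598 within the larger library set (423 of them shared), to 796 within the smaller set (186 shared) and to 2305 with library set as a term (1088 shared). It also moved with single libraries, to 554, 491 and 450 without WT replicate 1, 3 or 5, to 716 without LBD4-OE-11 replicate 2 and to 534 without LBD4-OE-17 replicate 2.

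The strongest rises in LBD4-OE were those of Potri.009G129900 (chromosome 9, 10614884 to 10617295, minus strand) and Potri.010G247400 (chromosome 10, 22173581 to 22176034, minus strand). Potri.009G129900 went from 2.61 ± 1.34 CPM in WT (SD, n = 5) to 21.2 ± 14.6 CPM in LBD4-OE (SD, n = 8), a log2 fold change of 3.00 ± 0.54 (SE, edgeR adjusted p = 0.00580), and stood at 46.3 ± 19.5 CPM in LBD11-OE (SD, n = 9). Its adjusted p was 0.101 in the limma fit with line as a random block and 0.130 within the smaller library set by edgeR. Potri.010G247400 moved in opposite directions under the constructs, from 1.83 ± 0.62 CPM in WT to 12.7 ± 7.56 CPM in LBD4-OE (log2 fold change 2.78 ± 0.41, SE, edgeR adjusted p = 7.540e-04) and to 0.547 ± 0.229 CPM in LBD11-OE (log2 fold change -1.74 ± 0.43, SE, edgeR adjusted p = 0.00369). Its rise in LBD4-OE had an edgeR adjusted p of 0.143 within the smaller set.

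The largest falls in LBD4-OE were smaller. Potri.010G051800 (chromosome 10, 8344852 to 8347129, minus strand) went from 5.55 ± 0.29 CPM in WT (SD, n = 5) to 2.31 ± 1.18 CPM in LBD4-OE (SD, n = 8), a log2 fold change of -1.27 ± 0.24 (SE, edgeR adjusted p = 0.00421), and to 0.636 ± 0.146 CPM in LBD11-OE (SD, n = 9). Its edgeR adjusted p was 0.106 within the smaller library set. Potri.017G051100 (chromosome 17, 3648262 to 3649463, plus strand) went from 116 ± 57.5 CPM in WT to 46.9 ± 14.6 CPM in LBD4-OE, a log2 fold change of -1.31 ± 0.31 (SE, edgeR adjusted p = 0.0260). Its WT libraries ran from 31.0 CPM in replicate 3 to 174 CPM in replicate 1, and its call was lost without WT replicate 1, 4 or 5 or LBD4-OE-17 replicate 2 (edgeR adjusted p = 0.0696, 0.0597, 0.050 and 0.0508) and with line as a random block (limma adjusted p = 0.123). Within the smaller set, against WT replicate 3 alone, its log2 fold change was 0.62 (edgeR adjusted p = 0.681).

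Of the 8 primary wall cellulose synthases 4 rose in LBD4-OE over all genes tested and 8 when adjusted over the list alone, with values of 0.15 to 0.45 and a median of 0.28 on the log2 scale. The count over all genes was 1 without WT replicate 3, without WT replicate 3 and LBD4-OE-11 replicate 1, without line LBD4-OE-14 or in limma voom with line as a random block (5 without the block), 7 with library set as a term, 3 within the smaller set, and 2 within the larger set, where the median was 0.23. It was also 2 without line LBD4-OE-11 or LBD4-OE-17, WT replicate 1 or 5, LBD4-OE-11 replicate 2, LBD4-OE-14 replicate 1 or LBD4-OE-17 replicate 2. The limma camera adjusted p was 2.325e-07, and adjusted p = 0.0802 with an estimated correlation. Of the 12 cambium regulators 1 rose and 1 fell over all genes, and 3 rose and 1 fell when adjusted over the list alone, with a median of 0.11, a camera adjusted p of 0.0331 and adjusted p = 0.223 with an estimated correlation. That call was also lost without line LBD4-OE-17 (0.154) and without WT replicate 3 and LBD4-OE-11 replicate 1 (0.125). With library set as a term 4 cambium regulators rose and 1 fell, and with single libraries left out 1 to 2 rose and 0 to 1 fell.

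Of the wood-forming lists 0 members changed in LBD4-OE over all genes by edgeR. Adjusted over the list alone, 2 of the 22 lignin enzymes fell and 1 of the 15 secondary wall transcription factors rose and 1 fell, while the 5 secondary wall cellulose synthases and 3 xylan synthases had 0 calls. At an unadjusted p under 0.05 edgeR had 1 secondary wall cellulose synthase, 1 lignin enzyme and 1 transcription factor higher, 2 lignin enzymes and 1 transcription factor lower, and 0 xylan synthases. DESeq2 called 2 lignin enzymes lower and 1 transcription factor higher, and limma voom called 0 members of these lists. Leaving out single libraries gave at most 1 lignin enzyme lower and 1 transcription factor higher or lower, and within the larger library set 1 lignin enzyme rose and 1 transcription factor fell. With library set as a term 1 secondary wall cellulose synthase and 1 transcription factor rose. In the single lines 1 lignin enzyme fell in LBD4-OE-11 and 2 in LBD4-OE-17, and 0 other members of these lists changed. Medians were 0.14 for the secondary wall cellulose synthases, -0.01 for the lignin enzymes, -0.03 for the xylan synthases and -0.09 for the transcription factors, and camera adjusted p-values were 0.380, 0.463, 0.589 and 0.463. Without line LBD4-OE-14 the lignin list passed in the downward direction (camera adjusted p = 0.0161), as it did within the smaller set (0.00114, median -0.29, 0 of 22 members by edgeR), but not in either case with an estimated correlation (adjusted p = 0.479 and adjusted p = 0.566), whereas its median was 0.07 within the larger set and 0.04 without WT replicate 3. The transcription factors had a median of 0.0083 within the larger set. Secondary wall cellulose synthases passed in the upward direction within the smaller set (camera adjusted p = 0.0241, and adjusted p = 0.261 with an estimated correlation), where 0 of 5 members passed edgeR's test. Of the clock genes 1 fell when adjusted over the list alone and neither did over all genes, with log2 fold changes of -0.27 ± 0.10 and 0.03 ± 0.10 (SE).

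The direct comparison of LBD11-OE with LBD4-OE found 2070 genes higher and 2276 lower under LBD11, of which 410 and 367 differed at least 2-fold. Of the 22 lignin enzymes 11 were higher and 0 lower under LBD11, both over all genes and over the list alone, with a median of 0.17 and a highest value of 0.83 ± 0.14 (SE), and 9 were higher within the larger library set, 4 within the smaller and 7 without line LBD4-OE-11 or LBD11-OE-14. The limma camera adjusted p was 3.898e-06, and adjusted p = 0.374 with an estimated correlation. Without line LBD11-OE-14 the count of genes that differed by edgeR fell to 2671, and within the larger library set it was 3662. Within the smaller set, where 3 libraries of LBD11-OE-2 stood against 3 of LBD4-OE-11, it was 726, of which 686 were among the 4346.

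Cellulose synthases were also higher under LBD11 than under LBD4, 2 of the 8 of the primary wall and 2 of the 5 of the secondary wall, over all genes and over the list alone. Their medians were 0.13 and 0.15, and camera adjusted p-values were 0.0233 and 0.123, with adjusted p = 0.374 and adjusted p = 0.419 with an estimated correlation. The secondary wall median turned negative without line LBD11-OE-14. The primary wall call was lost without line LBD4-OE-17 (0.0752) or LBD11-OE-1 (0.0590) and within the smaller library set (0.180), where 0 members of either list passed edgeR's test. Cambium regulators went the other way for 5 of 12, with 1 higher, a median of -0.03 and a camera adjusted p of 0.0569, and 0 passed either way within the smaller set. Of the secondary wall transcription factors 1 was higher and 1 lower over all genes, and 3 and 1 over the list alone or with library set as a term (camera adjusted p = 0.482). The 3 xylan synthases had 0 calls over all genes by edgeR, DESeq2 or limma voom, 1 higher at an unadjusted p under 0.05 and 1 higher over the list alone (camera adjusted p = 0.171). Both clock genes were lower under LBD11, by -0.45 ± 0.09 and -0.49 ± 0.08 (SE, edgeR adjusted p = 4.977e-04 and 1.061e-04). A difference in sample state between the constructs is thus not excluded either.

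The genes that differed most between the constructs were the same 4 as between LBD11-OE and WT. Potri.005G059900 had 2269 counts over the LBD11-OE libraries and 1 count over the LBD4-OE libraries, a ratio of 2083 (exact 95% interval 374 to 82323), and Potri.011G126000 had 1846 and 14 counts, a ratio of 121 with an upper bound of 222. Potri.011G161500 was lower in LBD11-OE than in LBD4-OE by -5.45 ± 1.15 and Potri.001G109300 by -4.80 ± 0.999 on the log2 scale (SE, edgeR adjusted p = 0.00229 and 0.00205). The falls of Potri.011G161500 and Potri.001G109300 did not pass with line as a random block (limma adjusted p = 0.517 and 0.424) or within the smaller library set (edgeR adjusted p = 0.266 and 0.350).

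Lines of a construct were compared with WT singly. LBD11-OE-14 changed 7010 genes, LBD11-OE-1 changed 5646 and LBD11-OE-2 changed 4295, while LBD4-OE-17 changed 687, LBD4-OE-11 changed 510 and LBD4-OE-14, with 2 libraries, changed 187. Secondary wall and lignin genes responded most in line LBD11-OE-14, where 4 of 5 secondary wall cellulose synthases rose with a median of 0.71 and 12 of 22 lignin enzymes with a median of 0.27. In LBD11-OE-1 and LBD11-OE-2 these counts were 2 and 2 for the cellulose synthases and 5 and 6 for the lignin enzymes, with 1 lignin enzyme lower in LBD11-OE-1. Of the 3 xylan synthases 2 rose in LBD11-OE-14 (median 0.26), 1 in LBD11-OE-1 (median 0.02) and 0 in LBD11-OE-2 (median 0.01). In edgeR's test of a difference among these lines 0 xylan synthases passed, with 2 at an unadjusted p under 0.05. In the same test 2 of the secondary wall cellulose synthases and 4 of the lignin enzymes passed. Primary wall cellulose synthases rose 8 of 8 in LBD11-OE-1 and LBD11-OE-14 and 4 of 8 in LBD11-OE-2, and 0 of 8 passed edgeR's test of a difference among the lines, also at an unadjusted p under 0.05.

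Over all genes 357 differed among the LBD11-OE lines and 51 among the LBD4-OE lines (edgeR, 2924 and 2614 at an unadjusted p under 0.05). Between lines of the larger library set, 445 genes differed for LBD11-OE-14 and LBD11-OE-1 and 10 for LBD4-OE-17 and LBD4-OE-14. LBD4-OE-11 and LBD11-OE-2 lie wholly in the smaller set. Across the sets, LBD11-OE-2 differed from LBD11-OE-1 in 2 genes (edgeR, 2143 at an unadjusted p under 0.05) and from LBD11-OE-14 in 174. LBD4-OE-11 differed from LBD4-OE-14 in 25 and from LBD4-OE-17 in 34. These counts do not show that few genes differ across the sets. The co-varying genes that define the sets averaged 0.96 to 1.97 log2 CPM in LBD11-OE-2 libraries and 6.39 to 6.55 in LBD11-OE-1 libraries. The line model's spread for such genes is widened by its WT group, in which WT replicate 3 is of the smaller set. Against the 1 WT library of that set, which is assumed to vary like the other groups, LBD4-OE-11 changed 713 genes and LBD11-OE-2 changed 3713. With library set as a term in the line model, which only the WT libraries can estimate, LBD4-OE-11 changed 3378 genes and LBD11-OE-2 changed 6180, and 190 genes differed among the LBD4-OE lines and 1223 among the LBD11-OE lines. Within the larger set LBD4-OE-14 changed 433 genes. The LBD4-OE-11 count was 1072 without WT replicate 3, 313 without WT replicate 4, 230 without WT replicate 5, 102 without its own replicate 2 and 162 without its replicate 3. The LBD4-OE-14 count was 420 without WT replicate 2, 5 without its replicate 1 and 11 without its replicate 2. The LBD4-OE-17 count was 391 without its replicate 1 and 187 without its replicate 2. Leaving out LBD11-OE-1 replicate 1 gave 3223 genes for that line, and leaving out LBD11-OE-2 replicate 1 or 2 gave 2176 or 2044 for its line. The 357 became 119 and 220 without LBD11-OE-14 replicate 2 or 3, and the 51 became 33 and 26 without LBD4-OE-11 replicate 2 or 3, 23 and 24 without LBD4-OE-14 replicate 1 or 2, and 26 and 31 without LBD4-OE-17 replicate 1 or 2.

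**Figure D2:**
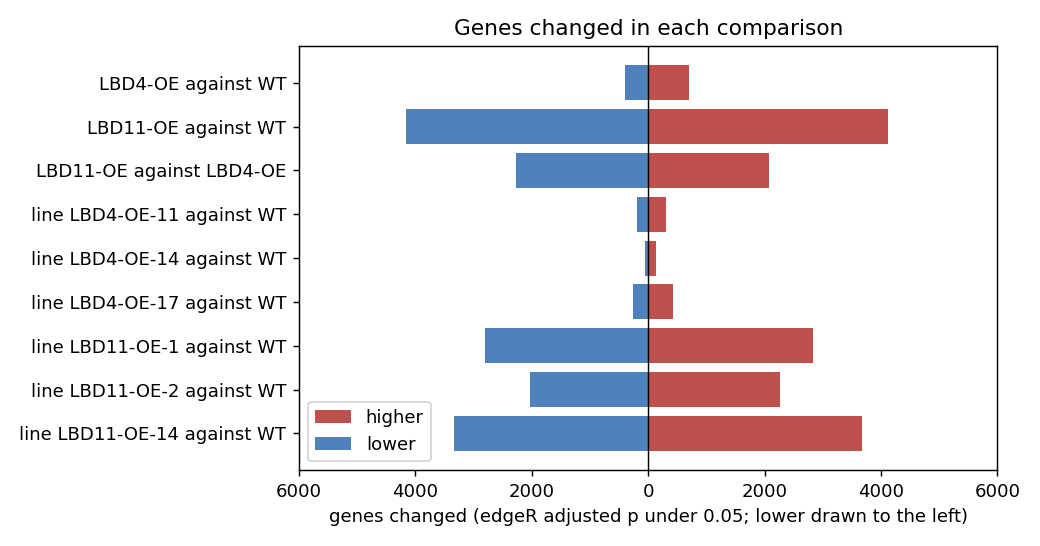
Number of genes changed at an edgeR adjusted p under 0.05 (horizontal axis) in each comparison, with genes higher in the first group drawn to the right in red and genes lower to the left in blue. LBD11-OE against WT reaches 4115 higher and 4166 lower, LBD4-OE against WT 694 and 403.

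Against WT, 572 genes rose and 322 fell in both, and 9 changed in opposite directions. Over all genes tested 77.7% had the same sign in both comparisons, against 71.6% in simulated unchanged groups. Independent lists of these sizes would share 111 higher and 65.5 lower genes. Simulated unchanged groups against the same WT libraries shared 0, a value that the absence of effects in them sets and that does not measure how far the common WT libraries raise the overlap. The log2 fold changes correlated across genes at r = 0.599, against 0.630 in the simulations, and genes are not independent replicates. Their covariance was 0.120 against 0.0260 simulated, a difference of 0.0941. The simulations drew each gene independently around 1 mean for all libraries, so they lack the co-variation of genes seen here. They cannot show how far a shift common to the WT libraries would raise the share of equal signs or the covariance. With the WT libraries shared out between the comparisons, the count of shared calls ran from 8 to 803 with a median of 68.5, the median correlation 0.412 and the median covariance 0.0981. Within the larger library set 426 genes were shared, and without WT replicate 1, 3 or 5 the 894 became 469, 365 and 367.

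A group of 54 co-varying genes was low in all LBD11-OE libraries. Its mean level was 2.06 ± 0.55 log2 CPM there (SD, n = 9), 4.33 ± 1.495 in WT (SD, n = 5) and 4.04 ± 1.80 in LBD4-OE (SD, n = 8). Of the 54 genes, 52 fell in LBD11-OE against WT by edgeR, 53 by DESeq2 and 37 by limma voom. In LBD4-OE 0 changed by any of these tools, and 0 at an unadjusted p under 0.05. It was also low in WT replicate 3 (1.77), LBD4-OE-11 replicate 1 (1.43) and LBD4-OE-17 replicate 2 (1.35). Potri.011G161500 and Potri.001G109300 belong to this group.

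A run of neighbouring genes on chromosome 13, from 15567206 to 15657495, was higher in the LBD11-OE stems. Of its 43 tested genes 41 rose in LBD11-OE, with a median of 2.45 on the log2 scale, and 23 in LBD4-OE, with a median of 1.65. The mean level of the run was 0.62 ± 0.52 log2 CPM in WT (SD, n = 5), 1.96 ± 0.91 in LBD4-OE (SD, n = 8) and 2.84 ± 0.57 in LBD11-OE (SD, n = 9). Within the larger library set 42 genes rose in LBD11-OE and 1 in LBD4-OE. The 12 tested genes within 100 kb on either side had a median of -0.01 in LBD11-OE.

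A further group of 9 co-varying genes divided the libraries without regard to construct. Its mean was at most 2.38 log2 CPM in 7 libraries (WT replicate 3, all 3 of LBD4-OE-11 and all 3 of LBD11-OE-2) and at least 5.02 log2 CPM in the other 15, and these are the smaller and larger library sets. With construct in the model, 3089 genes differed between the sets by edgeR, 1291 higher and 1798 lower in the smaller set, and 69 of them at least 2-fold. The sets were drawn from the same counts, and line was not in this model. As each line lies wholly in a single set, a set difference cannot be told apart from differences of LBD4-OE-11 and LBD11-OE-2 from the other lines. The sole WT library of the smaller set, WT replicate 3, lies apart on principal component 2.

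**Figure D3:**
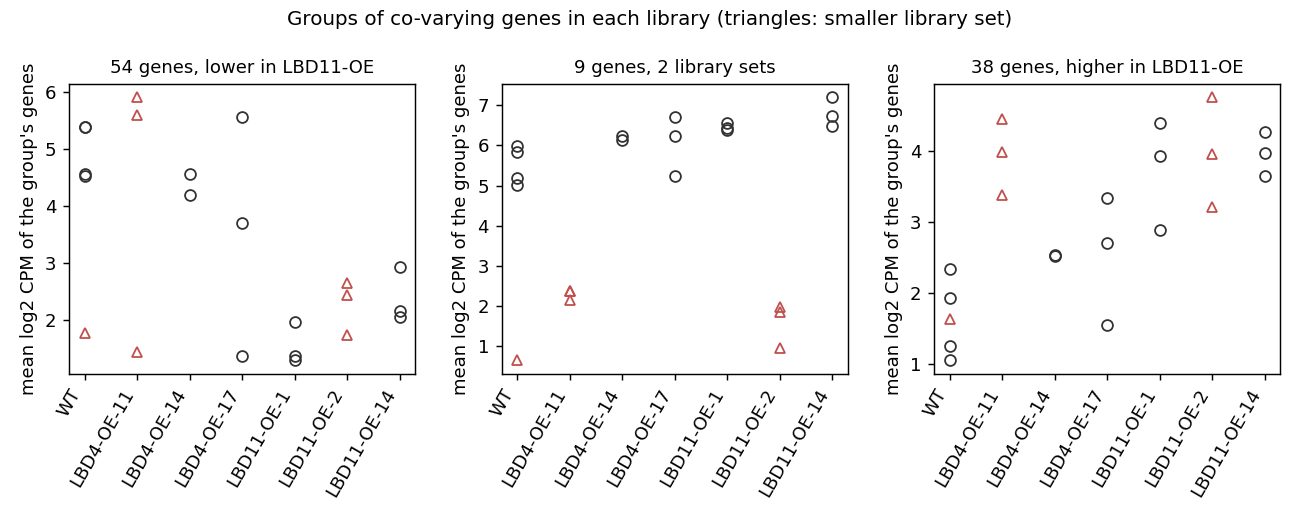
Mean log2 CPM (vertical axis) of 3 groups of co-varying genes in each of the 22 libraries, by line, with triangles for the 7 libraries of the smaller set and circles for the 15 of the larger. The 54-gene group is low in all LBD11-OE libraries and in 3 others, the 9-gene group separates triangles from circles, and the 38-gene group, which contains genes of the chromosome 13 run, has its highest values in LBD11-OE and LBD4-OE-11.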

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

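The groups of co-varying genes and the library sets were defined only after the data had been seen, and of the tests below those of a copy number change and of copies elsewhere for the chromosome 13 run, and that of its level in LBD4-OE-11, were chosen after their results were seen.

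Single libraries lay apart from their group, beyond Dixon's limit, in 8 of the 39 groups of values examined. In 2 of the 8 a single library held 1 or 2 counts and the others 0, which passes the limit by construction, and for the remaining groups chance gives about 1 in 20. LBD11-OE-2 replicate 1 had a count for 28374 genes, the nearest other LBD11-OE library for 28116. It also had the most counts of the LBD11-OE libraries, 38171334, with the next at 33677867, and more counts let more genes be detected. LBD4-OE-17 replicate 2 lay at -0.472 on principal component 1, and the nearest other LBD4-OE library at -20.5. On principal component 2, WT replicate 3 lay at -73.6 against 1.43 for the nearest WT library, and LBD4-OE-11 replicate 1 at -41.3 against 6.07. The level of Potri.009G129900 was 52.7 CPM in LBD4-OE-17 replicate 2, with the next LBD4-OE library at 25.6 CPM. Potri.005G059900 had 1 count, or 0.0295 CPM, in LBD4-OE-11 replicate 3 and 0 in the other LBD4-OE libraries, and Potri.011G126000 had 2 counts, or 0.0564 CPM, in WT replicate 1 and 0 in the other WT libraries. Potri.011G161500 was at 0.682 CPM in LBD11-OE-14 replicate 3, with the next LBD11-OE library at 0.271 CPM.

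Lines of the same construct differed in 51 genes for LBD4-OE and in 357 genes for LBD11-OE in the joint edgeR test. Potri.005G059900 differed among the LBD11-OE lines (edgeR adjusted p = 0.00220), with log2 fold changes against WT between 6.21 and 8.48.

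The 54-gene group was low in all 9 LBD11-OE libraries and in 3 of the 13 others, WT replicate 3 among them. If the library set caused the fall, it should have gone within the larger set, but 52 of the 54 genes were still lower in LBD11-OE there. As the genes were chosen to co-vary, this count reflects 1 shared profile. Within the smaller set the group showed no fall, with a mean of 1.77 log2 CPM in WT replicate 3, the sole WT library there, and 1.72, 2.43 and 2.64 in LBD11-OE-2. If WT replicate 3 were a mislabelled LBD11-OE library, it should lie near LBD11-OE over 2424 other genes that changed in every LBD11-OE line, but on a scale from the other WT libraries at 0 to LBD11-OE at 1 it lay at -0.0450, with LBD11-OE libraries at 0.777 to 1.17. Both explanations are thus argued against by the data as the whole cause, and a fall under LBD11 may be combined with a stem state that some WT and LBD4-OE samples share. Where on the stem each sample was taken, or how the trees stood, was not tested.

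The 2 library sets cut across WT, LBD4-OE and LBD11-OE, with a group of 9 genes lower by a median of -4.49 on the log2 scale in the smaller set. If the sets differ in something shared across constructs, LBD4-OE-11 and LBD11-OE-2 should depart from the other lines of their constructs in the same genes, and across genes these departures correlated at r = 0.299, against at most 0.163 for the other 8 pairs of an LBD4-OE and an LBD11-OE line. Each departure is taken from the other lines of the same construct, so these pairs are not independent of each other. WT replicate 3 departed from the other WT libraries in the same sense (r = 0.249 and 0.255). The LBD4-OE-11 departure averages unlike libraries, at -41.3, 6.07 and 21.4 on principal component 2, where WT replicate 3 lay at -73.6. These correlations were not computed without LBD4-OE-11 replicate 1, so its own state cannot be told apart from the library set. Over all genes tested, a length bias is argued against by a Spearman correlation of -0.0487 between the span of a gene on the genome and the difference. The 9 genes themselves were short, with a median span of 348 against 3539.5 for all tested genes, so a role of length is not excluded for them. Transcript length was not tested. A shared difference in growth, sampling or library preparation is a candidate explanation, and no label tells these apart.

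The chromosome 13 run was above WT in 6 of 6 lines by a median of over 0.5 on the log2 scale, which argues against a copy number change or an insertion in a single line, although all lines share the same WT libraries. The argument rests mainly on LBD11-OE-1, LBD11-OE-2 and LBD11-OE-14 (medians 2.37, 2.50 and 2.43), as within the larger set 1 gene of the run rose in LBD4-OE. Library set as the cause of the rise in LBD11-OE is argued against by the 42 of 43 genes still higher within the larger set. As the run was bounded by genes chosen to co-vary, this count reflects 1 shared profile. In LBD4-OE the rise was led by LBD4-OE-11 (median 2.40, against 0.85 and 0.95 in lines 14 and 17), which lies in the smaller set. The corresponding difference of LBD11-OE-2 from the other LBD11-OE lines was 0.0990 ± 0.469 (SE), too uncertain to tell whether the library set raised LBD4-OE-11. On other chromosomes 12 genes followed the run, which may reflect reads shared with copies elsewhere, and without the sequence this cannot be told apart from joint regulation. These genes lie on chromosomes 7, 11 and 17, and some on chromosomes 7 and 11 neighbour genes of the 9-gene group that divides the library sets. Genes of the run and of that group were short, with median spans of 717 and 348 against 3539.5 for all tested genes. Whether the run and that group have a common source was not tested.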

How the results depend on the processing

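Tests with the library set, those within the larger or smaller set and those without WT replicate 3 and LBD4-OE-11 replicate 1 together were chosen after the data had been seen, as were estimated correlations in other than the full construct fit, and the other alternatives were planned. Within the smaller set, whose 1 WT library is assumed to vary like the other groups, the falls of Potri.017G051100 in LBD4-OE and of Potri.011G161500 and Potri.001G109300 in LBD11-OE became log2 fold changes of 0.62, 5.62 and 1.56 (edgeR adjusted p = 0.681, 0.799 and 0.844), since all 3 genes were low in WT replicate 3. The value of 5.62 is set by the prior count and is no measured fold, as Potri.011G161500 had 0 counts in that library and 19 over LBD11-OE-2. In that set 7948 of the 8281 genes called for LBD11-OE against WT over all libraries had the same sign, called or not, as did 1078 of the 1097 for LBD4-OE against WT and 4338 of the 4346 between the constructs. Of the 2902 genes called both there and over all libraries for LBD11-OE against WT 1 had opposite directions, and in the other construct fits 0 did. No list that passed by camera in the full construct fit reversed under the alternatives run, but medians of lists short of the threshold in that fit changed sign. Among the latter is the lignin list in LBD4-OE, which passed downward in some alternatives and had a median above 0 in others. In LBD4-OE the lignin median of -0.01 rose to as much as 0.07 (larger set), that of the xylan synthases from -0.03 to 0.01 (smaller set) and that of the secondary wall transcription factors from -0.09 to 0.02 (without line LBD4-OE-11). In LBD11-OE the transcription factor median of 0.0096 fell to as little as -0.19 (smaller set), that of the cambium list from 5.503e-04 to -0.03 (without LBD11-OE-14 replicate 3) and that of the xylan synthases from 0.09 to -0.02 (without line LBD11-OE-14), and between the constructs the secondary wall cellulose synthases went from 0.15 to -0.03 (without line LBD11-OE-14). The cause of the changes below was not tested, except that a stricter threshold calls fewer genes by construction. Fits with fewer libraries called fewer genes in some cases and more in others.

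For LBD4-OE against WT the 1097 genes became 1944 with DESeq2, 456 with only these groups in the fit, 163 in limma voom with line as a random block (1040 without the block), 678 and 580 without line LBD4-OE-14 or LBD4-OE-17, 2305 with library set as a term, 598 within the larger set, 665 without the 2 libraries apart, 157 with a fold of at least 2 and 171 at an adjusted p under 0.01, with 450 to 1548 when leaving out single libraries of the groups compared, as in the ranges that follow. For LBD11-OE against WT the thresholds moved the 8281 genes to 1321 and 5041 and the smaller set to 3768, and leaving out single libraries gave 7033 to 8392. For LBD11-OE against LBD4-OE the 4346 became 777 and 2503 with these thresholds and 2671 without line LBD11-OE-14 and 726 within the smaller set, with 3765 to 4495 when leaving out single libraries of these constructs and 4214 to 4997 when leaving out single WT libraries, which enter this fit through the estimate of spread.

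For single lines DESeq2 gave 1208 (LBD4-OE-11), 763 (LBD4-OE-14) and 1266 (LBD4-OE-17), and fits with only the groups compared gave 86, 19 and 265, with 3508 for LBD11-OE-1 and 2675 for LBD11-OE-2. LBD4-OE-14 gave 370 without the 2 libraries apart and 433 within the larger set, and LBD4-OE-11 gave 3378 with library set as a term. Leaving out single libraries gave 102 to 1072 (LBD4-OE-11), 5 to 420 (LBD4-OE-14), 187 to 798 (LBD4-OE-17), 3223 to 5696 (LBD11-OE-1), 2044 to 4629 (LBD11-OE-2) and 4962 to 6970 (LBD11-OE-14). A line left with 1 library is assumed to vary like the other groups. Differences among lines became 186 (LBD4-OE) and 783 (LBD11-OE) without the 2 libraries apart, 190 and 1223 with library set as a term, and 23 to 53 and 119 to 339 when leaving out single libraries. The 894 genes shared by the constructs became 1558 with DESeq2, 1923 with library set as a term, 426 within the larger set, 506 without the 2 libraries apart, 365 to 1104 without single libraries, and 68.5 at the median, 8 at the lowest and 803 at the highest with WT libraries shared out.

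The replicate numbers do not pair the samples: deviations of libraries with the same number correlated at a mean of -0.00655 (57 pairs, 8 of them over 0.1) and those with different numbers at 0.00293, and 7 of 22 libraries correlated best with their own number. With the replicate block, LBD4-OE against WT gave 298 genes in the construct fit and 444 in the line fit, the lines LBD4-OE-11, LBD4-OE-14 and LBD4-OE-17 gave 92, 34 and 408, the LBD4-OE lines differed in 27 genes, 254 were shared by the constructs, and 5 of the 22 lignin enzymes rose in LBD11-OE. It also ended the call of Potri.017G051100 (edgeR adjusted p = 0.147).

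Camera calls that hung on a setting were the following. With an estimated correlation adjusted p-values were 0.0802 (primary wall) and 0.223 (cambium) for LBD4-OE against WT, 0.135 (primary wall) and 0.706 (lignin) for LBD11-OE against WT, and 0.374 for both lists between the constructs. Run also in the fits with line means, without each line, by library set and without the 2 libraries apart, the estimated correlation left 0 of 216 tests past the threshold, against 82 with the preset one, and the lowest adjusted p was 0.0700. For LBD4-OE against WT the cambium list also gave 0.154 without line LBD4-OE-17 and 0.125 without the 2 libraries apart, and the lignin list passed, downward, at 0.0161 without line LBD4-OE-14 and at 0.00114 within the smaller set, where the secondary wall cellulose synthases also passed (0.0241). For LBD11-OE against WT the secondary wall cellulose synthases passed with line means (0.00778), without line LBD11-OE-1 (0.0239) or LBD11-OE-2 (0.0248) with library set as a term (0.0221) and within the smaller set (0.00719), and the lignin list gave 0.0673 without line LBD11-OE-14 and 0.947 within the smaller set. Between the constructs the secondary wall cellulose synthases passed with line means (0.0429) and without line LBD4-OE-14 (0.0251) or LBD11-OE-2 (0.0486), the primary wall list gave 0.0752 without line LBD4-OE-17 and 0.0590 without LBD11-OE-1 and 0.180 within the smaller set, and the cambium list passed with line means (0.0429), without line LBD4-OE-11 (0.0231), LBD11-OE-1 (0.0356) or LBD11-OE-2 (0.0486), and within the larger set (0.0186). Depth limits genes with few counts: fold changes of genes near 0 in WT are known only within the wide intervals given.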

Other observations

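Of the tests below, the splits of the libraries were planned before their results were seen, and the positions of the LBD4-OE libraries and the fits by library set were looked at only afterwards.

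Libraries were placed on a scale from WT at 0 to the LBD11-OE mean at 1, over the genes that changed in every LBD11-OE line. Each WT library in turn was left out of both the choice of genes (2187 to 2708) and the scale, so that it took no part in them. It still shares whatever else sets WT apart as a group. Where a separate group of trees without an effect of the construct would lie is therefore not known. The left-out WT libraries lay at -0.0450 to 0.132. On these scales the 8 LBD4-OE libraries ran from 0.163 to 0.428, on each scale above the left-out WT library, and the LBD11-OE libraries lay at 0.773 or more.

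Other splits of the same libraries into groups of the same sizes were tested to see how often chance gives as many genes. For LBD4-OE against WT 1 of 100 splits, the real one with 1097 genes, gave as many, and the highest other gave 168. For LBD11-OE against WT 1 of 100 did, with 8281 genes against 3872 in the highest other, and for LBD11-OE against LBD4-OE 1 of 100, with 4346 against 6. Random assignment of single libraries thus gave fewer genes in every other split tried. The same held for LBD4-OE-17 (687 genes, highest other 279), LBD11-OE-1 (5646, highest other 1762), LBD11-OE-2 (4295, highest other 891) and LBD11-OE-14 (7010, highest other 2467), with 1 of 56 splits each. It also held for the differences among the LBD11-OE lines (357, highest other 326), with 1 of 100 tried out of 280 possible splits. As the splits exchange single libraries, which are nested in lines, they cannot exclude chance differences between lines or between batches of samples. With line as a random block, limma voom called 163 genes for LBD4-OE against WT. For LBD4-OE-11 against WT chance is not excluded, since 3 of 56 splits gave as many as the real 510 genes. The highest of them, with 2302 genes, put WT replicate 3 with LBD4-OE-11 replicates 1 and 2, all of the smaller library set, and points to a structure of the samples. Within that set LBD4-OE-11 differed from WT replicate 3 in 713 genes, and with library set as a term in the line model 3378 genes were called. Both counts rest on this 1 WT library in the smaller set, which lies apart on principal component 2, and they do not bear on whether chance gave the 510.

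The same splits were applied to the gene lists that passed by camera. For the primary wall cellulose synthases in LBD4-OE against WT, 4 of 100 splits, the real one among them, gave a camera p as small (real 3.875e-08, smallest other 1.431e-08). In LBD11-OE against WT 2 of 100 did (real 5.448e-07, smallest other 4.475e-07). These shares were small, but they were not adjusted for the number of lists and the splits ignore the lines, so chance is not excluded. With an estimated correlation the list passed in neither comparison (camera adjusted p = 0.0802 and adjusted p = 0.135). Chance is also not excluded for these genes in LBD11-OE against LBD4-OE (11 of 100, real 0.00778, smallest other 1.350e-04) or for the cambium regulators in LBD4-OE against WT (12 of 100, real 0.0110, smallest other 4.227e-04). The same holds for the lignin enzymes in LBD11-OE against WT (31 of 100, real 0.00120, smallest other 1.017e-08) and against LBD4-OE (16 of 100, real 6.496e-07, smallest other 1.499e-14). Members of both lists rise and fall together across the libraries, with a mean pairwise correlation of 0.553 for the primary wall cellulose synthases and 0.547 for the lignin enzymes, so that a preset correlation of 0.01 can make the camera p too small for either. A rise of either list may therefore rest on few independent events. That of the lignin enzymes under LBD11 also leans on line LBD11-OE-14 (camera adjusted p = 0.0673 without that line).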
